A study of Homo sapiens with 13 samples.

How the data were processed

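Gene expression was measured by RNA sequencing of poly(A) RNA from A549 cells in 13 libraries, 1 per group, grown in DMEM/F12 with serum, per the labels' protocols. Per the submitters' processing notes, the tools were RSEM 1.3.3 and Bowtie2 2.3.5.1 and the genome GRCh38.p13. The annotation release and the strand setting are not given in the sources used here, so antisense and overlapping genes may share reads. The authors deposited 3 tables of expected counts per gene, estimates that need not be whole and were not normalised. They hold the microRNA and CRISPRd libraries (39733 genes), the CRISPRi libraries (59577 genes) and the PRR11 and SKA2 libraries (17972 genes). Expected counts were rounded to whole numbers. In the CRISPRi table, 181 entries without a gene name held 0.355% and 0.431% of the counts and were left out of library sizes and tests. In the first table, 4840 entries are numbered copies of a symbol and hold 2.02% of the counts. They were summed per symbol, a choice made after the gene names were seen. The tables list different gene sets, so ratios were formed within a table, and ratios of controls across tables serve as background only.

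Library sizes were scaled by the trimmed mean of M values (TMM) within each table (edgeR 4.0.16, R 4.3.3). A gene was measured in a pair of libraries with at least 20 reads over both and at least 1 CPM in either. It was called when the log2 ratio of CPM plus 0.5 was at least 1 in size, which is a 2-fold change, and the exact (Clopper-Pearson) 95% interval of the ratio excluded equality. Log2 values are on this scale and understate changes of low genes, while folds are plain CPM ratios. Where a library had 0 counts, the fold was taken against 3 counts in that library and written as at least that fold. Such a fold leaves out the counting error of the other library, so the exact lower bound can be smaller. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. At totals of 18672601 to 21811946 counts, 3 counts are 0.136 to 0.165 CPM. No p-value was computed between single libraries.

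The comparisons, the size rule, 31 gene lists and the first alternatives below were fixed before the data were examined. The first list is the unit itself, and the others cover PI3K-AKT (core, brakes, receptors and ligands, FOXO targets), matrix, cell cycle (G1/S, G2 and mitosis, kinetochore), p53, apoptosis, epithelial, mesenchymal, interferon, NF-kB, stress response, hypoxia, cholesterol, NRF2, TGF-beta, immediate early, microRNA targets and processing, lineage, 17q22 neighbours and markers of other cells or of RNA selection (fibroblast, immune, HEK293, mitochondrial, ribosomal protein, histone). Some genes stand in more than 1 list. The median log2 ratio of each list was placed among 10000 random lists of the same size drawn within 20 bins of mean expression, as a description of these libraries. Named genes were the targets, up to 4 called members per list, and the 5 higher and 5 lower genes of each additive fit. They also included the 8 higher and 8 lower genes with at least 5 CPM whose counting bound nearest equality lay farthest from equality. Clone-based, pseudogene and Y-linked names and XIST were excluded from the ranking of pairs. Some genes that this rule names are not reported here.

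The lentiviral sets form 2 by 2 layouts and were fitted with both labels as terms by edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment and 1 residual degree of freedom, on genes at 1 CPM in at least 2 libraries. Each label's coefficient was tested against that residual, so its p-value weighs it against the departure of these single libraries from additivity, which may be technical. The biological coefficient of variation was 0.0231 in the PRR11 and SKA2 set and 0.165 in the microRNA set. DESeq2 1.42.0 was an alternative. Gene positions and 3′ UTRs came from GENCODE release 29 on GRCh38, whose build family matches the submitters' notes. Seed sites (7mer or 8mer) were searched in the longest 3′ UTR of coding genes, and the difference between genes with and without a site was compared with 10000 sets matched in 10 bins of expression and 10 of UTR length, and with 20 shuffled words. Shared controls were simulated 20 times with unchanged negative binomial counts. Chromosome windows of 50 genes at 5 CPM or more, in steps of 25, were compared with 100 shuffled gene orders. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

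The size rule and the additive fit were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. At counting noise the size rule found 100% of 4-fold changes and 34 to 47% of 2-fold changes in the 9 pairs, with 1 to 10 false calls. At the dispersion of the additive fits, false calls were 74 to 90 outside the PRR11 and SKA2 set and 2 to 3 within it. The additive fit found 100% of 2-fold changes for PRR11 (13329 genes, 5 false calls) and 53% for miR301a (14649 genes, 2 false calls), and 100% of 4-fold changes in both. The first alternatives were other scalings, pseudocounts of 0.1 and 2, a minimum of 5 CPM, a 1.5-fold threshold, 8mer sites and other additive models. Copies left apart, exchanged labels and the other control library of the table were added after the data were seen.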

Results

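Poly(A) RNA was sequenced from 13 cultures of A549, a human lung adenocarcinoma cell line, to ask how a gene unit on chromosome 17 acts on gene expression and on PI3K-AKT signalling, a growth and survival pathway. The unit holds PRR11, a proline-rich protein of the cell cycle, SKA2, a subunit of the spindle and kinetochore associated complex, and the microRNAs miR-301a and miR-454. In GRCh38, SKA2 lies at chromosome 17, 59109951 to 59155269, on the minus strand, and PRR11 at 59155499 to 59204705 on the plus strand, so the genes are transcribed away from each other. MIR454 (59137758 to 59137872) and MIR301A (59151136 to 59151221) lie on the strand of SKA2, and both sit in introns of all 6 annotated SKA2 transcripts, without overlapping an exon. The libraries form 4 sets. The first holds guide RNAs that repress the shared promoter (CRISPRi_PRR11+SKA2 promoter-sgRNA#1) and a mock guide (CRISPRi_Mock sgRNA). The second holds lentiviral expression of PRR11, SKA2 or both (LV-PRR11, LV-SKA2, LV-P+S) and LV-vector-PS. The third holds lentiviral expression of miR-301a, miR-454 or both (LV-miR301a, LV-miR454, LV-3+4) and LV-vector-34. The fourth holds knockouts of the microRNA precursors (CRISPRd_miR301a-#2, CRISPRd_miR454-#1) and CRISPRd_Control. Total counts ran from 18672601 to 21811946 per library. Each group is 1 library, so no difference between a treated and a control library has a replicate check, and each ratio compares libraries, not conditions.

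The targeted genes were read first. In the CRISPRi library, PRR11 had 14 counts against 2029 in the mock library, or 0.643% of the control level (exact 95% counting interval 0.351 to 1.08%). SKA2 had 5 counts against 1594, or 0.292% (0.0948 to 0.683%). In the overexpression set the target genes moved little. PRR11 stood at 109% of the vector in LV-PRR11 (103 to 116%) and at 110% in LV-P+S (104 to 117%). SKA2 was below the vector in both libraries meant to raise it, at 84.4% in the library labelled LV-SKA2 (77.9 to 91.4%) and at 88.7% in the library labelled LV-P+S (82.0 to 96.0%). Taken at face value, these counts go against the labels of both libraries for SKA2. Whether the authors' reference counted the introduced cDNAs, which can differ in sequence from the gene, is not given in the sources used here, so none of these 4 values measures the introduced copies with certainty.

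**Figure D1:**
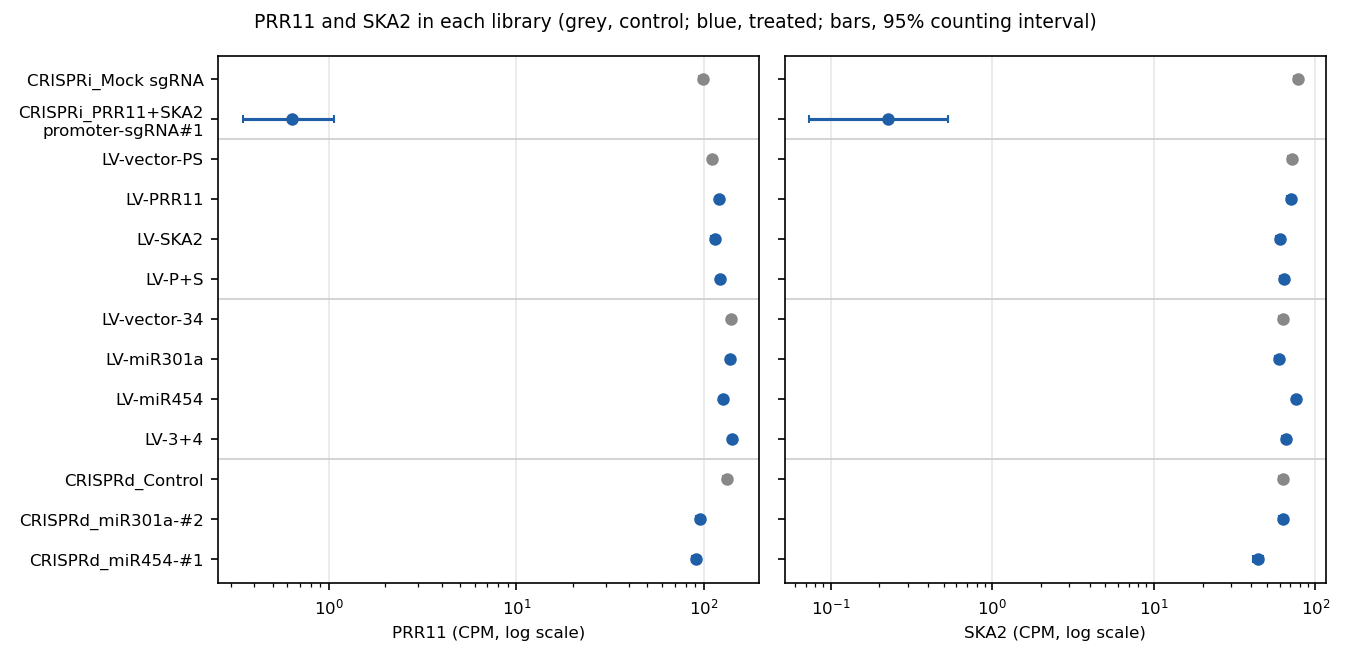
PRR11 (left) and SKA2 (right) in each of the 13 libraries, as CPM (reads scaled to library size) on a log axis; grey points are controls, blue points are treated libraries and bars are 95% counting intervals. PRR11 lies at 0.635 CPM and SKA2 at 0.227 CPM in the CRISPRi library, against 98.8 and 77.6 CPM in its mock control.

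The microRNA loci were not analysed here in the PRR11 and SKA2 set. Among the 9 libraries of the other sets, their reads were seen in the 3 treated libraries of the lentiviral microRNA set. MIR301A had 29 counts in the library labelled LV-miR301a and 34 in the library labelled LV-3+4, at least 9.48-fold and 11.3-fold above the 0 counts of LV-vector-34, taken at 3 counts. MIR454 had 468 counts in LV-miR454, at least 157-fold above the vector. It also had 28 counts in the library labelled LV-miR301a (at least 9.16-fold) and 0 in the library labelled LV-3+4. LV-miR454 had 0 MIR301A counts, and the vector, both CRISPRi libraries and all 3 CRISPRd libraries had 0 of either locus. Such a count allows up to 0.165 CPM in CRISPRd_miR454-#1, the largest of the 3-count limits. The knockouts are thus unchecked by these counts, and the MIR454 reads go against the labels of LV-miR301a and LV-3+4. Poly(A) RNA holds no mature microRNA, so the reads show locus transcripts only. The host gene SKA2 was at 121% of the vector in LV-miR454 (112 to 131%), at 99.1% of the control in CRISPRd_miR301a-#2 (91.5 to 107%) and at 70.0% in CRISPRd_miR454-#1 (64.0 to 76.5%). PRR11 was at 72.4% (68.1 to 76.9%) and 68.5% (64.4 to 72.9%) of the control in the CRISPRd libraries. Beside them, the 15 measured neighbours on 17q22 had 0 past the size rule described next, with median log2 ratios of -0.13 (percentile 19.2 of matched random lists) in CRISPRd_miR301a-#2 and -0.36 (percentile 0.200) in CRISPRd_miR454-#1. HEATR6 was at -0.75 and -0.60 and RPS6KB1 at -0.39 and -0.78. Against LV-vector-34 these medians were -0.16 and -0.26.

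A gene was called higher or lower when its ratio was at least 2-fold and its counting interval excluded equality. By this rule 1414 genes were higher and 894 lower in the CRISPRi library, of 14977 measured. LV-PRR11 had 24 higher and 16 lower of 13397, the library labelled LV-SKA2 had 19 and 15 of 13465, and the library labelled LV-P+S had 18 and 17 of 13426. The library labelled LV-miR301a had 53 and 55 of 14776, LV-miR454 had 443 and 510 of 14910, and the library labelled LV-3+4 had 42 and 53 of 14715. CRISPRd_miR301a-#2 had 1013 and 625 of 15070, and CRISPRd_miR454-#1 had 992 and 465 of 15009. As background, 646 genes passed the same rule between the control libraries LV-vector-34 and CRISPRd_Control, which share a table. Between controls of different tables, 919 to 2230 genes passed.

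**Figure D2:**
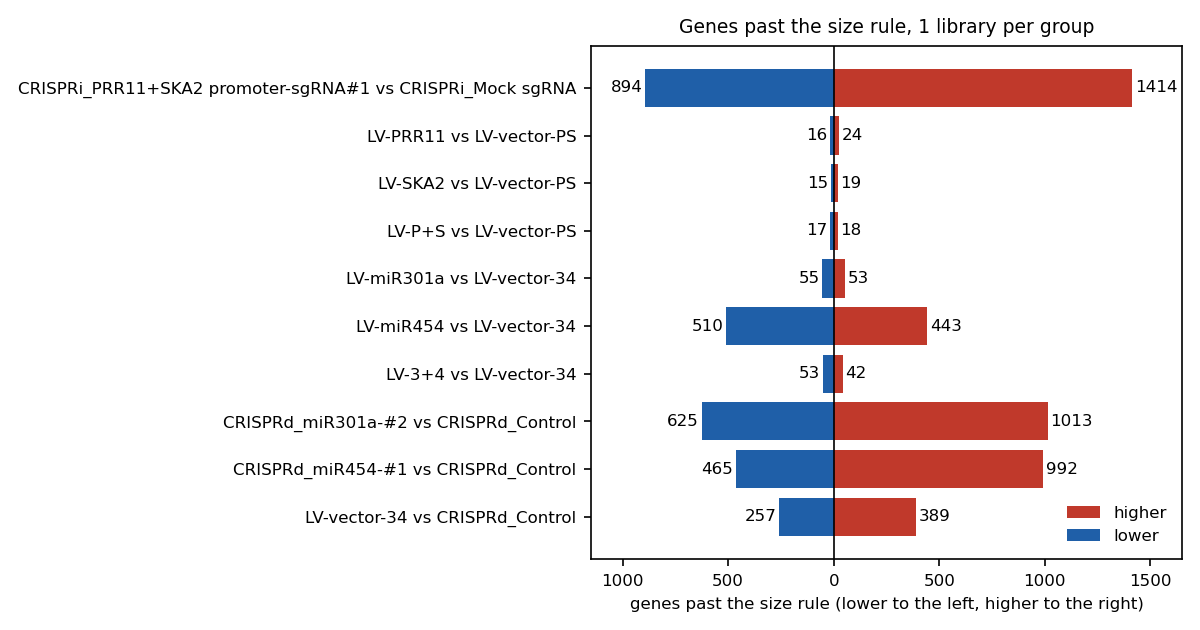
Number of genes past the size rule in each comparison, with lower genes to the left of 0 and higher genes to the right. The last bar compares the control libraries LV-vector-34 and CRISPRd_Control (389 higher, 257 lower), a background larger than the counts of the libraries labelled LV-PRR11, LV-SKA2, LV-P+S, LV-miR301a and LV-3+4.

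Repression of the PRR11 and SKA2 promoter asked what is lost and gained when both genes fall silent. Proliferation genes were lower as a group in the CRISPRi library, while genes of the extracellular matrix, interferon response and inflammation were higher. Ranked by the counting bound nearest equality among genes at 5 CPM or more, the higher genes included LCE3D, a late cornified envelope gene (98.2 against 0.584 CPM, 168-fold, interval 96.1 to 326), IL33, an alarmin cytokine (85.4-fold, 51.6 to 153), PSG4, a pregnancy-specific glycoprotein (34.7-fold, 23.4 to 53.9), and DYSF, which repairs muscle membranes (33.3-fold, 22.9 to 50.4). PPBP, a platelet chemokine, was 43.8-fold higher (19.9 to 120) and IGFL1 44.7-fold (18.9 to 139). LCE3E (2 control counts, ratio 264, 72.8 to 2186) and IVL, which encodes involucrin (1 control count, ratio 117, 20.7 to 4673), rest on few control reads. LCE3D, LCE3E and PSG4 belong to families of near-identical genes, so the split of reads among copies is uncertain. After PRR11 and SKA2, the lower genes ranked in the same way were led by DDC, which makes dopamine and serotonin (51.7-fold, 24.8 to 130), MUC5B, a gel-forming airway mucin (22.6-fold, 18.7 to 27.7), TERT, the catalytic subunit of telomerase (19.5-fold, 10.7 to 39.7), and VIL1, which bundles actin in microvilli (10.4-fold, 7.35 to 15.2). E2F2, a driver of S phase entry, was 10.2-fold lower (7.31 to 14.7) and CPLX2, a regulator of vesicle fusion, 7.39-fold lower (7.19 to 7.59).

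Cell cycle groups moved together. Of 32 measured G1/S and replication genes, 26 were lower and 0 higher, with a median log2 ratio of -1.76. MCM10 (-2.84), CDC45 (-2.32) and CDC6 (-2.22), which build the replication machinery, were among them. Of 32 genes of G2 and mitosis, 31 were lower (median -1.60), including the proliferation marker MKI67 (-2.37), the spindle motor KIF11 (-2.25), the checkpoint kinase BUB1B (-2.08) and CDK1 (-2.06). Of 26 kinetochore genes, 19 were lower (median -1.26), with SKA3, a partner of SKA2 in its complex, at -1.99, SPC24 at -1.89 and the centromeric histone CENPA at -1.84. Each of these medians lay below all 10000 random lists matched on expression. Of 27 p53 targets, 13 were higher and 0 lower (median 0.97, percentile 100), among them TP53INP1 (2.31), TP53I3 (1.95), the cyclin-dependent kinase inhibitor CDKN1A (1.80) and the death receptor FAS (1.60). Of 9 measured histone genes whose messages are largely not polyadenylated, 7 were higher (median 1.32), such as H2BC4 (2.34) and H2AC6 (1.77). This set has near-identical copies and was chosen as a readout of how RNA was selected. RNA selection itself was not measured, and the cause of the rise was not tested.

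Matrix and inflammatory genes were higher. Of 32 extracellular matrix and integrin genes, 20 were higher and 0 lower (median 1.28), with the integrin ITGB3 at 3.23, osteopontin (SPP1) at 2.59 and fibronectin (FN1) at 2.22. Of 21 mesenchymal genes, 11 were higher (median 1.12), among them TAGLN (3.34), the transcription factor SNAI2 (3.25) and the protease MMP2 (3.17). Fibroblast markers moved with both groups, 8 of 10 being higher (median 1.67), such as FBN1 (3.20) and COL5A1 (2.04). Of 30 interferon response genes, 17 were higher (median 1.23), including IFI27 (3.21), IFI6 (3.16) and the antiviral GTPase MX1 (2.67). Of 23 NF-kB and inflammation genes, 11 were higher and 1 lower (median 0.98), with the chemokines CXCL1 (3.58) and CXCL8 (3.37) and the cytokine IL6 (2.90). Of 24 TGF-beta targets, 10 were higher and 1 lower (median 0.76), including CCN2 (2.10) and PMEPA1 (2.08). Each of these 6 medians lay at percentile 100.

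The PI3K-AKT genes did not move as a block. Of 29 core pathway genes, 0 were higher and 0 lower (median -0.18, percentile 27.4). Of 19 brakes on the pathway, PIK3IP1, an inhibitor of PI3K (3.21), the lipid phosphatase INPP4B (1.87) and INPP5D (1.10) were higher, while PHLPP1, a phosphatase of AKT, was lower (-1.25). The median of the brakes was -0.11 (percentile 46.9). Of 29 receptors and ligands, 8 were higher and 5 lower, with the growth factors IGF2 (3.10), PDGFB (2.35) and FGF1 (3 control counts, ratio 16.5, 5.34 to 82.3) against the receptor FGFR3 (-2.35). Their median, 0.30, turned to -0.04 when genes under 5 CPM were left out. Of 20 targets of FOXO, the transcription factors that AKT restrains, 7 were higher and 3 lower (median 0.49, percentile 99.9), with FBXO32 (3.65), TXNIP (2.08) and GADD45A (2.02) among the higher ones.

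Among the remaining groups of the CRISPRi library, NRF2 targets of the antioxidant response had 0 higher and 5 lower of 28 (median -0.54), among them GCLC (-1.54) and GPX2 (-1.27). Cholesterol and lipid genes had 0 higher and 3 lower of 25, among them the lipid synthesis regulator SREBF1 (-1.20). Epithelial genes were split, 3 higher and 3 lower of 17, with KRT19 (2.62) and CLDN4 (2.45) against TJP3 (-1.82) and E-cadherin (CDH1, -1.59). Apoptosis genes had 4 higher and 1 lower of 27, with BMF (1.84) against BIRC5 (-1.34). Stress response genes had 4 and 1 of 25, hypoxia and glycolysis genes 3 and 1 of 28, and immediate early genes 2 and 2 of 24, with NR4A1 at -1.89. Of 29 published targets of the microRNA family, 9 were higher and 3 lower (median 0.34, percentile 99.9), with INHBA (3.82) and the lipid exporter ABCA1 (2.56) highest. Alveolar and airway lineage genes had 2 higher and 2 lower of 12, with the mucin MUC5AC (-2.70) against the basal cell genes KRT5 (2.55) and TP63 (2.13). Of the neighbours on 17q22, 1 of 15 was higher (YPEL2, 1.67) and 0 lower. Immune markers had 2 higher of 4, and markers of HEK293, a line used to package lentivirus, 3 higher and 1 lower of 10. Of 13 mitochondrial messages, 29 ribosomal protein genes and 12 microRNA processing genes, 0 passed the rule.

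Lentiviral PRR11 and SKA2 asked whether more of either gene changes expression. Few genes differed from the vector, and most of those named were readthrough transcripts or members of duplicated families, whose counts are uncertain. In LV-PRR11, HTD2 was higher (3.8-fold, 2.73 to 5.41), and ZNF197, a zinc finger gene, was lower (7.87-fold, 4.50 to 14.9). The readthrough NME1-NME2 was higher in the library labelled LV-SKA2 (5.86-fold, 4.67 to 7.41), and FOSB, an immediate early transcription factor, was lower (3.18-fold, 2.46 to 4.16). ABHD14A-ACY1 was at least 33.6-fold higher there, against 0 control counts. NME1-NME2 was also higher in the library labelled LV-P+S (2.57-fold, 2.01 to 3.31), where GATD3A was 4.11-fold lower (2.65 to 6.57) and the interferon-induced IFITM1 2.87-fold lower (1.49 to 5.88). FOSB and IFITM1 were the only members of the fixed lists past the rule in these 3 libraries.

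Small shared shifts were seen in the lists. Medians of G2 and mitosis genes (-0.09, percentile 0) and of G1/S genes (-0.06, percentile 1.32) lay low in the library labelled LV-SKA2. G1/S genes were at -0.08 (percentile 0) and kinetochore genes at -0.06 (0.730) in the library labelled LV-P+S, where 7 of 9 HEK293 markers lay below 0 (median -0.10, percentile 2.00). In LV-PRR11, cholesterol genes were at -0.07 (percentile 0), immediate early genes at -0.09 (0.0100), p53 targets at 0.07 (99.9) and FOXO targets at -0.08 (0.330). Beside these, 27 of 29 ribosomal protein genes lay above 0 in LV-PRR11, with a median of 0.06 (percentile 99.99). The PI3K-AKT core had 0 of 29 genes past the rule in each of the 3 libraries, with medians of -0.0152, -0.00103 and -0.0183.

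The PRR11 and SKA2 set holds 1 library per combination of labels, so the p-values below measure no spread between replicate cultures. They weigh an effect against the departure of these libraries from additivity, which may be technical. An additive fit over the 4 libraries, which leaves 1 residual degree of freedom, estimated each lentiviral label's effect across the other (edgeR quasi-likelihood test, 13329 genes). It called 154 genes for the PRR11 label, 41 higher and 113 lower, and 786 for the SKA2 label, 477 higher and 309 lower, at an adjusted p under 0.05. For PRR11, AP3S2, which sorts vesicle cargo, was higher in both libraries carrying the label (log2 0.43, edgeR adjusted p 5.6e-08). The Nogo receptor relative RTN4RL2 was lower in both libraries carrying the label than in both others (log2 -0.24, edgeR adjusted p 3.4e-09). MUC5B had a negative PRR11 coefficient (log2 -0.37, edgeR adjusted p 8.1e-14), being lower in LV-PRR11 than in the vector and in LV-P+S than in LV-SKA2. For the SKA2 label, TM4SF20, a membrane protein (log2 0.44, edgeR adjusted p 1.3e-29), the neuronal splicing factor RBFOX3 (0.57, 6.3e-22), MUC5B (0.44, 1.2e-19) and the tight junction protein CLDN2 (0.31, 2.3e-12) were higher in both libraries carrying it. The adhesion molecule CEACAM6 (log2 -0.41, edgeR adjusted p 7.6e-12) and the Polycomb protein BMI1 (-0.46, 1.0e-07) were lower in both. MUC5B stood at 106 CPM in the vector, 84.0 in LV-PRR11, 147 in LV-SKA2 and 110 in LV-P+S. RTN4RL2 stood at 377, 330, 461 and 375 CPM in the same order, so LV-P+S was hardly below the vector. Readthrough or copied genes were also among the top calls, with LOC102724219 (1.03) first by p among the higher genes for PRR11 and NME1-NME2 (1.58) for SKA2. Whether AP3S2 and BMI1 share reads with readthrough transcripts was not checked, so their calls are uncertain too. DESeq2 called 0 genes for PRR11, with 95 at an unadjusted p under 0.05, and 45 for SKA2, of the 925 it gave an adjusted p. As the SKA2 counts were lower in both libraries labelled for it, and may leave out introduced copies, these calls give no direction for a gain of SKA2.

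Lentiviral microRNA expression asked which genes each microRNA lowers. LV-miR454 was far from its vector, while the libraries labelled LV-miR301a and LV-3+4 were close to it. In LV-miR454, FOSB was 33.7-fold higher (24.3 to 48.0), IGFL1 47.2-fold (18.1 to 175), the trefoil peptide TFF1 19.3-fold (11.1 to 36.8), the chorionic gonadotropin gene CGB8 17.7-fold (11.2 to 29.8) and LDLRAD2 14.0-fold (10.6 to 18.8). Keratin 19 (KRT19) was 13.9-fold higher (10.3 to 19.2), at 33.5 CPM against 2.41 in LV-vector-34, but stood at 18.0 CPM in CRISPRd_Control, the other control library of the table. Lower genes were BCHE, a cholinesterase (35.1-fold, 14.7 to 109), SHISA3 (25.6-fold, 17.1 to 40.3), the guidance cue NTN1 (12.2-fold, 6.79 to 24.2), ADGRV1 (9.91-fold, 5.59 to 19.1) and the chemokine CCL20 (9.60-fold, 6.80 to 13.9). CGB8, SERF1A (at least 39.4-fold higher), SULT1A4 (3 counts, ratio 129 lower, 43.9 to 629), RBM14-RBM4 (at least 56.5-fold lower) and RN7SL2 (22.3-fold lower) share reads with copies or neighbours and are uncertain. Against CRISPRd_Control, FOSB, IGFL1, TFF1, CGB8 and LDLRAD2 were also called higher and CCL20 lower. KRT19 (0.88), BCHE (-0.72), NTN1 (-0.60) and ADGRV1 (0.24) were not past the rule there, nor were SERF1A and RN7SL2, and SHISA3 was higher (1.44).

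Of 24 TGF-beta targets, 9 were higher and 0 lower in LV-miR454, with CYR61 at 1.87, the integrin ITGB6 at 1.83 and PMEPA1 at 1.75. Of 24 immediate early genes, 6 were higher and 1 lower, including EGR1 (1.91), ATF3 (1.51) and JUN (1.45). Of 31 matrix genes, 7 were higher and 2 lower, among the higher ones THBS1 (2.21), and of 20 mesenchymal genes 4 were higher and 1 lower. Fibroblast markers moved with them, 4 of 7 being higher and 1 lower (COL5A1 2.36, FBN1 1.89), but against CRISPRd_Control 2 of 7 were higher, with COL5A1 (0.62) and FBN1 (0.78) not past the rule. COL5A1 stood at 212 CPM in LV-miR454, 40.9 in LV-vector-34 and 138 in CRISPRd_Control. Against CRISPRd_Control, TGF-beta targets again had 9 higher and 0 lower, immediate early genes 7 and 1, matrix genes 9 and 2, and mesenchymal genes 4 and 1. NF-kB and inflammation genes had 1 higher and 5 lower of 22, and their median of -0.12 lay within the matched random lists (percentile 5.99), with CCL20 (-2.97), CCL5 (-2.28) and ICAM1 (-1.88) against IL11 (1.75). G1/S genes had a median of 0.37 with 1 of 32 higher (CCNE2, 1.14), and cholesterol genes a median of 0.43, with 24 of 25 above 0 and 0 past the rule. Beside them, 29 of 29 ribosomal protein genes lay below 0, with a median of -0.18 (percentile 0.0100). Against CRISPRd_Control the medians were 0.02 for G1/S genes, 0.50 for cholesterol genes, 0.09 for ribosomal protein genes and -0.87 for NF-kB genes. The PI3K-AKT core had 0 of 29 past the rule. Among the brakes INPP4B was higher (1.62) and DDIT4, an inhibitor of mTOR, lower (-1.17), and among receptors and ligands PDGFC (2.21) and PDGFB (2.12) were higher and IGF2 (-1.52) and ERBB3 (-1.18) lower. FOXO targets had 2 higher and 3 lower of 20 (median -0.09), PDK4 lowest at -2.25. Against CRISPRd_Control the FOXO targets had 4 higher and 1 lower of 20 (median 0.39). Of the genes named from these PI3K-AKT and FOXO lists, INPP4B, PDGFB and PDK4 were also called against CRISPRd_Control, and DDIT4, PDGFC, IGF2 and ERBB3 were not. LV-miR454 had 831 calls against CRISPRd_Control, and 345 (36.2% of the 953) kept their direction while 18 were opposite. Of its 64 named genes, 36 kept their direction and 2 were opposite (SHISA3 and INHBA).

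The type I collagen gene COL1A1 was 2.56-fold higher in the library labelled LV-miR301a (2.31 to 2.85), COL3A1 2.07-fold (1.73 to 2.48), the succinate receptor SUCNR1 3.52-fold (2.39 to 5.31) and RAB43, a trafficking GTPase, 3.78-fold (2.83 to 5.11). SENP3, a SUMO protease, was 2.13-fold lower (2.05 to 2.22) and IMPG2 3.17-fold lower (2.17 to 4.72). Matrix genes had 2 higher of 30 (median 0.24) and fibroblast markers 2 of 6 (median 0.65), the same collagens. NF-kB genes (median 0.21), p53 targets (0.13) and G2 and mitosis genes (-0.13) had 0 past the rule. Ribosomal protein genes had a median of -0.12 there (percentile 0), with 28 of 29 below 0. PLSCR3 was 2.17-fold higher in the library labelled LV-3+4 (1.85 to 2.56), the glutathione-degrading CHAC1 2.39-fold (1.85 to 3.12) and IMPG2 4.43-fold lower (2.88 to 7.07). Its p53 targets had a median of -0.10 and stress response genes one of 0.13, with CHAC1 past the rule. Swings of SULT1A3 (12.7-fold and 13.1-fold higher), RN7SL1, RN7SL2, RGPD6, RAD51L3-RFFL and CDRT4 in these libraries concern copied or overlapping genes. Whether SENP3, RAB43 and PLSCR3 share reads with readthrough transcripts was not checked, so their ratios are uncertain too. The PI3K-AKT core had 0 of 29 genes past the rule in both.

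The additive fit over these 4 libraries (edgeR quasi-likelihood test, 14649 genes) called 0 genes for the miR301a label, with 577 at an unadjusted p under 0.05. DESeq2 called 2, SENP3 (log2 -1.38, DESeq2 adjusted p 1.3e-07) and RN7SL1 (-2.90, 0.0115). For the miR454 label edgeR called 1 gene, the pseudogene GTF2IP1, at 0 CPM in both libraries carrying the label and at 37.0 and 27.1 CPM in the others (edgeR adjusted p 0.0253, 358 genes at an unadjusted p under 0.05). That call was lost without the CPM minimum, without the miR301a term, with copies left apart and with exchanged labels, each giving 0. GTF2IP1 was also low in CRISPRd_Control, which carries no miR-454 construct by its label. CRISPRd_miR301a-#2 (66.0 CPM) and CRISPRd_miR454-#1 (13.8 CPM) had log2 ratios of 6.46 and 4.25 over that control. A low level was thus not particular to the miR454 label. DESeq2 called 1, SULT1A4 (log2 -7.38, DESeq2 adjusted p 1.1e-08). These few genes were named after their values were seen, and the contrary MIR454 counts bear on every direction here.

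Both microRNAs share a seed, the short stretch that pairs with target 3′ UTRs. In the library labelled LV-miR301a, the median log2 ratio of 2571 genes with a seed site minus that of genes without was -0.00426, while 10000 sets matched on expression and UTR length gave a median of 0.0233 (percentile 0). In the library labelled LV-3+4 the difference was -0.0147 against 0.00400 (percentile 0). In both, all 20 shuffled words of the same bases gave higher values. For LV-miR454 the difference was -0.00979 (percentile 80.4). For the CRISPRd libraries it was 0.0375 (percentile 80.0) and 0.0183 (95.5). Genes with the longer 8mer site were at -0.0492, -0.0403 and -0.0409 in the libraries labelled LV-miR301a, LV-miR454 and LV-3+4, and at 0.0812 and 0.0490 in the CRISPRd libraries. Without a microRNA construct by their labels, LV-PRR11 was at -0.0113, LV-SKA2 at -0.0246, LV-P+S at -0.0079 and the CRISPRi library at 0.0017. No matched sets were drawn for these 8mer values. All these shifts are at most a few percent in size. Medians of published targets of the microRNA family lay within their matched random lists in the microRNA and CRISPRd libraries. They were -0.0349 (percentile 17.7) in the library labelled LV-miR301a, 0.00218 (45.8) in LV-miR454 and 0.0200 (74.4) in the library labelled LV-3+4. In CRISPRd_miR301a-#2 and CRISPRd_miR454-#1 they were 0.131 (94.5) and -0.00612 (56.5). The difference for all seed sites was -0.0222 in the library labelled LV-SKA2 (percentile 0.920), where 13 of 20 shuffled words lay at or below it, and -0.00846 in the CRISPRi library (80.6).

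**Figure D3:**
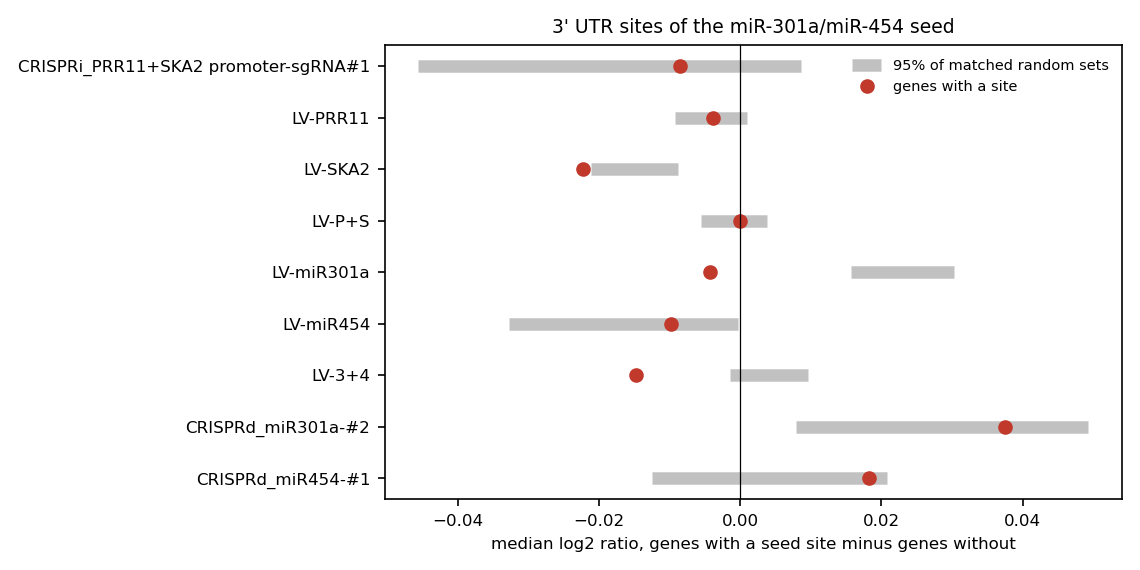
Difference in median log2 ratio between genes with and without a 3′ UTR seed site of miR-301a and miR-454 (red points), with 95% of 10000 matched random gene sets as grey bars, for the 9 comparisons. The libraries labelled LV-miR301a (-0.00426) and LV-3+4 (-0.0147) lie below their bars, and so does the library labelled LV-SKA2 (-0.0222).

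Knockout of the microRNA precursors asked what is released when each is lost. Both CRISPRd libraries differed widely from their control. MUC5B was higher and keratin 19 (KRT19) lower in both, whether against CRISPRd_Control or LV-vector-34, while FOXO targets were higher as a group mainly against CRISPRd_Control. In CRISPRd_miR301a-#2, the fibrinogen chains FGG (118-fold, 98.3 to 143), FGB (95.3-fold, 83.0 to 110) and FGA (77.4-fold, 69.2 to 86.8), which form blood clots, were higher. So were the adhesion molecule CHL1 (366-fold, 143 to 1345), the cell surface mucin MUC16 (147-fold, 57.0 to 541) and RFX6, a transcription factor of the gut and pancreas (at least 97.2-fold). MUC5B reached 4662 against 107 CPM (43.4-fold, 41.6 to 45.4). KRT19 was at least 111-fold lower, the liver carboxylesterase CES1 at least 70.5-fold, N-cadherin (CDH2) 121-fold (58.6 to 302) and the neuronal pentraxin NPTX1 110-fold (55.6 to 256). The basement membrane collagen COL4A6 had 1 count (ratio 737, 132 to 29147). In CRISPRd_miR454-#1, MUC5B was 32.1-fold higher (30.8 to 33.5), the cystatin CST1 43.0-fold (38.1 to 48.6), the carboxypeptidase CPVL 91.6-fold (39.0 to 284), TXNIP 73.9-fold (31.3 to 229) and MUC5AC 10.3-fold (9.66 to 11.1). NPTX1 was 72.0-fold lower (41.0 to 140), SLFN11, which blocks stressed replication forks, 44.9-fold (23.5 to 98.9), the kinase CAMK1 40.5-fold (20.3 to 94.6) and the repressor PRDM1 23.5-fold (11.2 to 59.2). KRT19 had 1 count there (ratio 328 lower, 58.5 to 12982). UGT1A6, SULT1A3 and C4B share exons or near-identical copies and are uncertain. Sizes depended on the control. Against LV-vector-34 the log2 ratios in CRISPRd_miR301a-#2 were 4.38 for FGG, 4.11 for FGB, 4.44 for FGA and 4.38 for CHL1, in place of 6.77, 6.51, 6.23 and 6.73. That of MUC5AC was -0.87 there, in place of 1.26, and 1.22 in CRISPRd_miR454-#1, in place of 3.36. KRT19 was at -2.54 in CRISPRd_miR301a-#2 and -2.39 in CRISPRd_miR454-#1, in place of -5.21 and -5.06. CES1 was at -2.82 in CRISPRd_miR301a-#2, in place of -4.57. Against LV-vector-34, 52 of the 76 named genes of CRISPRd_miR301a-#2 and 47 of the 69 of CRISPRd_miR454-#1 were called in the same direction, with 1 opposite in each (EGR1 and CTH).

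FOXO targets were higher in both, 9 of 19 in CRISPRd_miR301a-#2 (median 0.78) and 8 of 19 in CRISPRd_miR454-#1 (median 0.86), with 0 lower. TXNIP (4.02 and 4.67), PDK4, which diverts pyruvate from the mitochondrion (3.0 and 3.58), the receptor ERBB3 (2.56 and 3.17) and SESN3 (2.3 and 1.92) led the group. Against LV-vector-34 the FOXO medians fell to 0.15 and 0.23, with 6 higher and 1 lower of 20, and 5 higher and 1 lower of 20. Of the 29 PI3K-AKT core genes, IRS2, an adaptor of the insulin receptor, was higher in CRISPRd_miR301a-#2 (1.51, not past the rule against LV-vector-34), and 0 passed in CRISPRd_miR454-#1. Receptors and ligands of the pathway had 6 higher and 2 lower of 27 in CRISPRd_miR301a-#2 (median 0.36, percentile 99.9), and 6 and 2 against LV-vector-34 (median 0.38). In CRISPRd_miR454-#1 they had 5 higher and 1 lower of 26 (median 0.08, percentile 80.4), and 6 and 3 of 27 against LV-vector-34. ERBB3 and the ligand ANGPT1 (1.91 and 1.80) were higher in both libraries and PDGFB (-2.62 and -2.31) lower, against either control. Of the 17 measured brakes, 0 passed the rule in either library, and against LV-vector-34 1 was higher and 2 lower, and 0 and 1, of 19. Mesenchymal genes had 1 higher and 8 lower of 19 in CRISPRd_miR301a-#2, with CDH2, MMP2 (-3.15), ZEB2 (-2.75) and SPARC (2 counts, ratio 52.2 lower, 14.1 to 436) among the lower ones, and 2 higher and 4 lower of 20 in CRISPRd_miR454-#1. Against LV-vector-34 these were 0 higher and 7 lower of 19, and 4 higher and 4 lower of 21. Of 6 fibroblast markers in CRISPRd_miR301a-#2, 0 were higher and 2 lower (COL5A1 -3.29), but their median of -0.32 lay within the matched random lists (percentile 9.22), and against LV-vector-34 there were 1 higher and 3 lower. Interferon genes had 12 higher and 0 lower of 31 in CRISPRd_miR454-#1 (median 0.90, against LV-vector-34 0.94), including IFITM1 (3.11) and OASL (2.00), and 4 higher and 1 lower of 26 in CRISPRd_miR301a-#2. NF-kB genes had 9 higher and 3 lower of 25 in CRISPRd_miR454-#1 (median 0.70), with IL6 (2.90), CCL20 (2.28) and CXCL8 (1.77). In CRISPRd_miR301a-#2 they had 3 higher and 6 lower of 23 (median -0.48), a median that turned to 0.19 against LV-vector-34. Hypoxia and glycolysis genes had 4 and 6 higher of 28 and 0 lower, including CA9 (2.48 and 3.10) and SLC2A3 (3.51 and 2.52), and against LV-vector-34 had 2 higher and 0 lower, and 2 higher and 1 lower. There CA9 was at 0.19 and 0.81, SLC2A3 at 1.05 and 0.06, and the list medians fell from 0.30 and 0.33 to -0.03 and 0.09. G1/S medians were -0.39 and -0.49, with 1 and 0 of 32 lower, and -0.19 and -0.23 against LV-vector-34, with 0 past the rule. Immune markers had 3 of 5 and 2 of 4 higher, with CD68 at 1.36 and 1.72, and against LV-vector-34 2 higher each. HEK293 markers had 2 higher and 0 lower of 9 in CRISPRd_miR454-#1 (median 0.41, percentile 97.7), CRMP1 (1.86) and NEFL (2.15), of which NEFL was at 0.01 against LV-vector-34. In CRISPRd_miR301a-#2 they had 1 higher and 1 lower of 9. Total-count scaling moved the median of all genes to -0.08 and -0.12 in these libraries.

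The knockouts share their control library, so their ratios move together by chance. The CRISPRd libraries had 804 calls in common, 255 of them lower. NPTX1 and KRT19 were lower in both, and MUC5B and the coagulation factor F5 (5.27 and 4.76) higher. Unchanged libraries simulated against the shared control gave 7.70 common calls on average, and independent lists of these sizes would share 71.8. The covariance of the ratios was 0.369, against 0.0637 in the simulation, and Pearson's r across genes, which are not independent, was 0.746 against 0.504. Part of the excess may come from the shared control. Each simulation here and below used 1 dispersion for all genes, from the additive fits (that of the microRNA set for the CRISPRd libraries). The residual of those fits also holds departures from additivity. The simulation held no real difference of CRISPRd_Control from other controls, such as the 646 calls against LV-vector-34. Its values are therefore a limited background and do not exclude the control as a source. In the lentiviral sets, r was 0.336, 0.434 and 0.536 among the PRR11 and SKA2 libraries (simulated 0.522 to 0.525), with 12 to 14 common calls, against at most 0.150 in the simulation and 0.0307 to 0.0349 for independent lists. The covariances were 0.0112, 0.0132 and 0.0174, against 0.0111 to 0.0112 in the simulation. In the microRNA set r was 0.185 and 0.223 between LV-miR454 and the libraries labelled LV-miR301a and LV-3+4, and 0.597 between the latter (simulated 0.510 to 0.513), with covariances of 0.0240, 0.0275 and 0.0367 against 0.0639 to 0.0646. These pairs had 38, 36 and 44 common calls, against 7.40, 6.60 and 6.55 in the simulation and 2.61, 2.40 and 0.266 for independent lists.

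Pairs of comparisons without a shared library could be set against each other. By their labels the perturbations of a pair are opposite, except that CRISPRi and the CRISPRd knockouts are both losses. For CRISPRi and the library labelled LV-P+S, SKA2 counts were below the control in both, though introduced copies may not have been counted. Across 12299 genes, the CRISPRi ratios and those of the library labelled LV-P+S had r of 0.0875 (bootstrap interval 0.0640 to 0.110), with 3 genes called in opposite directions and 2 in the same. Ratios of the library labelled LV-miR301a and of CRISPRd_miR301a-#2 had r of 0.0804 (0.0575 to 0.105), with 15 genes called in opposite directions and 17 in the same. For LV-miR454 and CRISPRd_miR454-#1, r was -0.0669 (-0.0998 to -0.0378), with 141 genes called in opposite directions and 120 in the same, against 34.9 and 33.1 for independent lists. The library labelled LV-3+4 had r of -0.0558 (-0.102 to -0.0213) with CRISPRd_miR301a-#2, with 18 opposite and 8 same calls, and of -0.0423 (-0.0815 to -0.00216) with CRISPRd_miR454-#1, with 13 and 11. The CRISPRi ratios had r of 0.130 (0.103 to 0.155) with CRISPRd_miR454-#1, with 189 opposite and 206 same calls, against 70.3 and 75.7 for independent lists. With CRISPRd_miR301a-#2 the sign depended on the measure, with r of -0.0282 (-0.0555 to -0.00240), r of 0.0580 over genes at 10 CPM or more and a Spearman rho of 0.120. This pair had 289 opposite and 160 same calls, against 82.5 and 85.2 for independent lists. For the other pairs, in the order given, rho was 0.127, 0.129, -0.0735, -0.0519, -0.0569 and 0.247. Genes are not independent replicates, so the intervals describe these libraries only.

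**Figure D4:**
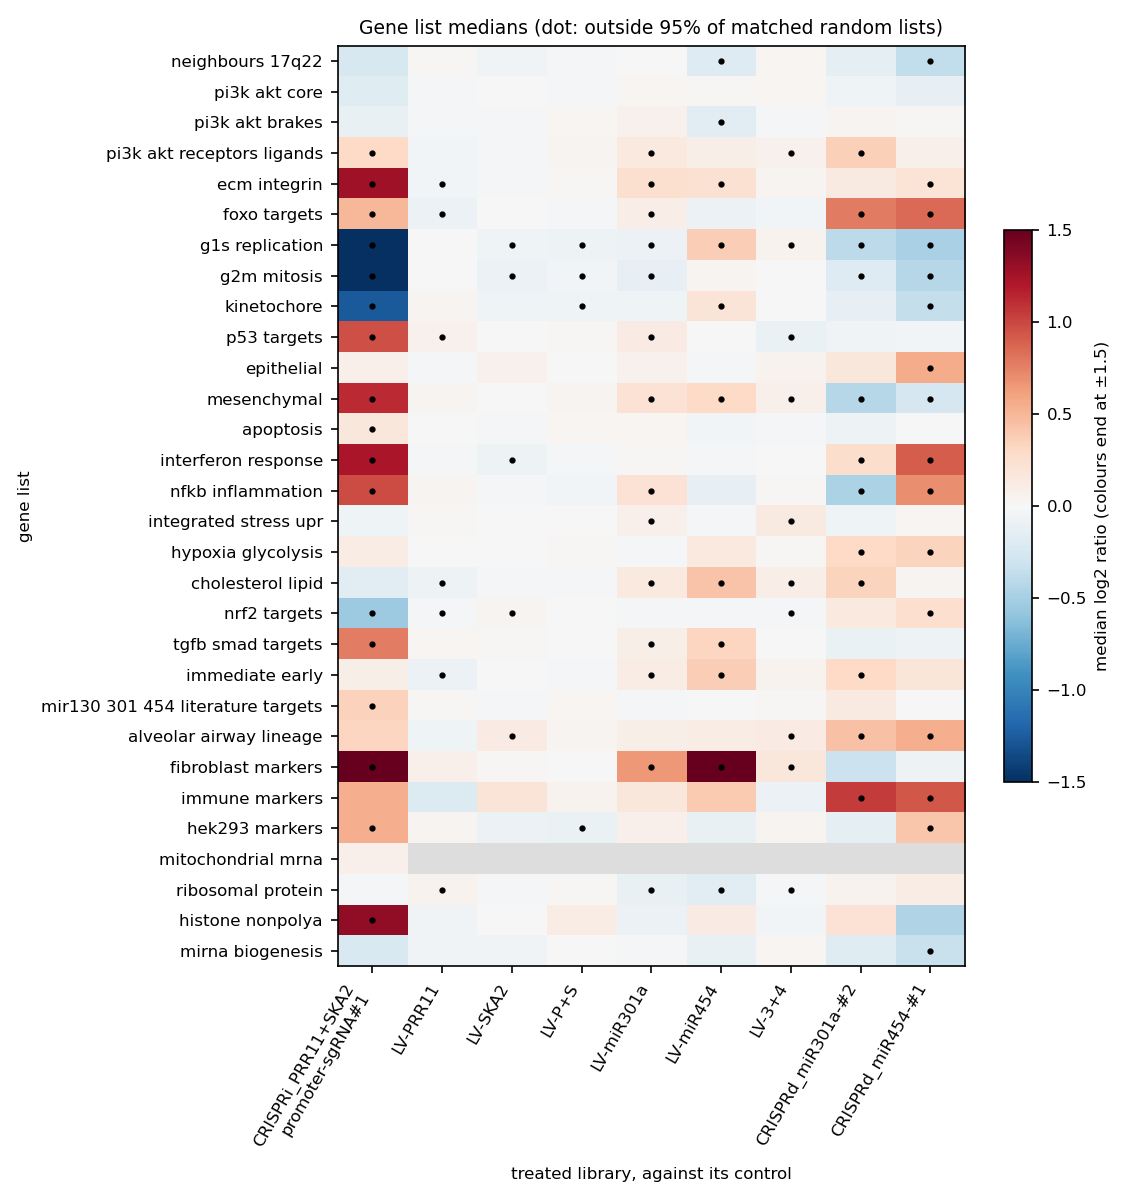
Median log2 ratio of each gene list (vertical axis) in the 9 comparisons (horizontal axis), in red where higher and blue where lower, with colours ending at 1.5 in size; dots mark medians outside 95% of 10000 matched random lists, and grey cells were not measured. Of 262 medians, 96 carry a dot, against 13.1 for random lists drawn without regard to function. Genes of a list can vary together and some stand in more than 1 list, so 13.1 is not a chance expectation. The deepest colours are in the CRISPRi column (G1/S -1.76, fibroblast markers 1.67) and for fibroblast markers in LV-miR454 (1.57, which is 0.62 against CRISPRd_Control).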

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

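The tests on the control library and on seed sites among the higher genes of the CRISPRd libraries, and on the ZNF10 level of the mock library, were chosen after the result was seen. The list medians below were singled out because they lay on opposite sides of 0, each outside its matched random lists, in treated libraries of 1 set. No difference among them was tested, as each group is 1 library. NRF2 targets were at -0.03 in LV-PRR11 and 0.04 in the library labelled LV-SKA2, a difference of -0.0734. G1/S genes were at -0.08 in the library labelled LV-miR301a and 0.37 in LV-miR454 (0.02 against CRISPRd_Control), a difference of -0.45, and at 0.05 in the library labelled LV-3+4, a difference of -0.14. The p53 targets were at 0.13 in the library labelled LV-miR301a and -0.10 in the library labelled LV-3+4, a difference of 0.23. NF-kB genes were at -0.48 in CRISPRd_miR301a-#2 and 0.70 in CRISPRd_miR454-#1, a difference of -1.18, though the former median turned to 0.19 against LV-vector-34.

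The library labelled LV-miR301a held 28 MIR454 counts and the library labelled LV-3+4 held 0, the reverse of their labels. If these labels had been exchanged, the ratio of the former over the latter might follow that of LV-miR454 over its vector, but r across 14440 genes was -0.0340 (-0.0936 to 0.0164, Spearman -0.0482), which leaves an exchange open. Mixing of LV-miR454 reads into the library labelled LV-miR301a would need 5.82%, and the median share over 71 genes raised in LV-miR454 was 5.40% (1.80 to 6.59%), against 0.928% (0 to 2.62%) in the library labelled LV-3+4. That test is not specific, since CRISPRd_Control, with 0 MIR454 counts, gave 19.8% (12.1 to 26.1%), and mixing does not account for the missing MIR454 of LV-3+4. A construct other than the label names remains open and untested.

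The CRISPRd libraries differed from their control in 1638 and 1457 genes, while their target loci gave 0 counts in all 3. Against LV-vector-34, the lower share of calls that kept their direction was 53.9%, near the bound of 50%. Those calls argue against the control library as the whole cause, though that bound was set after the result was seen. The interval of the share (51.5 to 56.3%) counts genes as independent, which they are not, so it does not measure the uncertainty between libraries. Of the calls, 9.2% in CRISPRd_miR301a-#2 and 12% in CRISPRd_miR454-#1 (10.3 to 13.9%) lay in chromosome windows beyond shuffled orders. This is under the 50% foreseen for copy-number differences as the main cause, against 6.9% and 10.7% of all measured genes. The test cannot decide, since a call needs a 2-fold change and window medians stayed smaller, as on chromosome 21 (0.52 to 0.58 in CRISPRd_miR454-#1). Copy-number differences thus stay open. Lifted repression through the shared seed stays open, as the shares of higher genes with a seed site, 17.9% and 15.6%, lay low at percentiles 8.67 and 4.60 but within their matched ranges. Differences between separately derived cell lines, and indirect effects of losing each microRNA, may also contribute and were not tested.

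ZNF10, a zinc finger gene at chromosome 12, 133130575 to 133159465, was 12.8-fold higher in the CRISPRi library than in the mock (95.1 against 7.45 CPM, 10.8 to 15.1). A candidate explanation is reads of the CRISPRi repressor, whose KRAB domain commonly derives from ZNF10: the mock library stood 2.90 times (2.09 to 4.09) above the highest of the 11 other libraries (2.56 CPM), which carry no such construct by their labels, though they come from other tables. A rise of the surrounding region was argued against by a median of 0.16 (0.01 to 0.28) over the 10 nearest measured genes, of which only the overlapping AC026786.1 (2.42) was more than 2-fold higher. A shared rise of zinc finger genes was argued against by a median of 0.0246 (-0.0230 to 0.0868) over all measured ones. On this reading the CRISPRi library may hold more of the repressor than its mock, which was not tested.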

How the results depend on the processing

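Alternatives chosen after seeing the data were copies left apart, exchanged labels, LV-vector-34 as the CRISPRd control and CRISPRd_Control as the LV-miR454 control; all others were planned. Of 2427 alternative values, 2275 stayed within the spread or on the same side, 148 moved and 4 reversed. No paired analysis was possible because each group is 1 library, which also rules out leaving out replicates, and no table held several columns per sample. Depth limits low genes most: with 1 to 3 counts in a library, the counting interval of a ratio spans an order of magnitude or more, as for IVL (20.7 to 4673). TMM, DESeq2 size factors and total counts left each count of called genes within 1.5 times.

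Libraries are given here by their labels. Taken at face value, the SKA2 counts go against those of LV-SKA2 and LV-P+S, though introduced copies may not have been counted. The MIR454 counts go against those of LV-miR301a and LV-3+4, for a reason left open above. A pseudocount of 2 CPM gave 1472 calls in the CRISPRi library, 11 in LV-PRR11 (5 higher, 6 lower), 8 in LV-SKA2 (3 and 5), 6 in LV-P+S, 33 in LV-miR301a, 428 in LV-miR454, 30 in LV-3+4, and 1012 and 828 in the CRISPRd libraries. A pseudocount of 0.1 gave 76, 80 and 68 in the PRR11 and SKA2 set, 197 in LV-miR301a and 179 in LV-3+4. Leaving out genes under 5 CPM gave 5, 7 and 3 (2 higher, 1 lower) in the PRR11 and SKA2 set, 28, 522 and 26 in the microRNA set, and 1038 and 872 in the CRISPRd libraries. A larger pseudocount and a CPM minimum remove low genes by construction. A 1.5-fold threshold, looser by construction, gave 5278 for CRISPRi, 158, 186 and 140 for LV-PRR11, LV-SKA2 and LV-P+S, 381, 2725 and 338 for LV-miR301a, LV-miR454 and LV-3+4, and 3691 and 3407 for CRISPRd. Between controls it gave 1822 within the table, and 3968, 4719, 4608, 2603 and 2758 across tables. With copies left apart, LV-miR301a had 334 calls and LV-3+4 had 320. Against LV-vector-34 the CRISPRd libraries had 1331 and 1394 calls.

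The additive PRR11 count fell from 154 to 0 with DESeq2 and to 2 without the SKA2 term, and the SKA2 count from 786 to 45 and 38. The miR301a count was 2 with DESeq2. The single miR454 call became 0 without the CPM minimum, without the miR301a term, with copies left apart and with exchanged labels. The cause was not tested.

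With genes under 5 CPM left out, the CRISPRi medians of PI3K-AKT receptors and ligands and of HEK293 markers reversed, to -0.0401 and -0.0833. List medians outside the matched range, 96 in all, stayed outside on the same side in 94 with a pseudocount of 2, 93 with total counts and 85 with the 5 CPM minimum.

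With 8mer sites, the seed difference was -0.0113 in LV-PRR11, -0.0246 in LV-SKA2, -0.0079 in LV-P+S, -0.0492 in LV-miR301a, -0.0403 in LV-miR454 and -0.0409 in LV-3+4. It was 0.0812 and 0.0490 in the CRISPRd libraries, and turned from -0.0085 to 0.0017 in the CRISPRi library. After the median of the shuffled words was subtracted, it was -0.0270 in LV-miR301a and turned sign in LV-SKA2 (0.0028), LV-miR454 (0.0079), CRISPRd_miR301a-#2 (-0.0145), CRISPRi (0.0160) and LV-P+S (0.0008). Of these, only the LV-SKA2 difference had lain outside its matched range and is counted among the 4 reversals. With genes at 10 CPM or more, r was 0.1815 for CRISPRi and LV-P+S, 0.1506 for the miR301a pair, 0.0580 for CRISPRi and CRISPRd_miR301a-#2, a reversal, and 0.2297 for CRISPRi and CRISPRd_miR454-#1. With a pseudocount of 2 these were 0.1153, 0.1111, -0.0014 and 0.1595. The cause was not tested.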

Other observations

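The pair described here, and its repeat against another control, were chosen after the result was seen. The CRISPRi and LV-miR454 libraries, which share neither a control nor a table, had 251 genes called in the same direction, 181 higher and 70 lower, against 45.8 for independent lists. Opposite calls numbered 46, against 45.3. Higher in both were IGFL1 (3.94 and 3.87), the contractile light chain MYL9 (2.74 and 3.18) and the metalloproteinase inhibitor TIMP3 (2.82 and 2.51). Lower in both were ASB4 (-1.79 and -2.42) and the scavenger receptor SCARA5 (-1.99 and -1.69). These 5 genes were also called when CRISPRd_Control replaced LV-vector-34 as the control of LV-miR454. KRT19 (2.62 and 3.55) and RTN4RL2 (-2.42 and -1.55) were not, at 0.88 and 0.10, and 36.2% of all LV-miR454 calls kept their direction. With that control the libraries had 185 calls in the same direction, against 41.3 for independent lists, and 73 opposite, against 39.3. Pearson's r across 12847 genes was 0.225 (0.201 to 0.250) and Spearman's rho 0.133, and with the other control 0.177 and 0.158. The G1/S median was -1.76 in the CRISPRi library and 0.37 in LV-miR454, or 0.02 against CRISPRd_Control.

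In chromosome windows of 50 genes, 22 of 406 lay above shuffled orders in the library labelled LV-SKA2 and 0 below. Of these, 12 were on chromosome 19, with medians of 0.09 to 0.14. The rest were spread over chromosomes 1, 8, 11, 16, 17 and 22, with medians of 0.08 to 0.12. In the library labelled LV-P+S, 0 of 405 windows lay beyond shuffled orders. In CRISPRd_miR454-#1, 35 of 416 windows lay beyond, 17 of them lower on chromosome 17, 8 on chromosome 9 and 4 on chromosome 19, and 3 higher on chromosome 21 (0.52 to 0.58). In CRISPRd_miR301a-#2, 21 of 414 did, with 9 lower on chromosome 17 and 7 lower on chromosome 9. The control LV-vector-34 against CRISPRd_Control had 24 of 410, with 4 lower on chromosome 9 and 4 on chromosome 19, and the CRISPRi library 0 of 413.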
